A study of Mus musculus with 32 samples.

How the data were processed

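RNA was measured by sequencing in 32 libraries from mouse embryos, each library made from the forebrain tissue of 1 embryo: dorsal telencephalon at embryonic day (E) 12.5 and cortex at E15.5. The libraries form 8 groups. Labelled Kat6b knockout and wild-type embryos came from the C57BL/6 background, with 3 libraries per genotype at E12.5 and 5 at E15.5. Embryos carrying the Tg(Kat6b) transgene and their wild-type controls came from a mixed FVBxBALB/c background, with 4 libraries per genotype and age. Per the labels, RNeasy columns gave total RNA, a TruSeq RNA kit gave the libraries, and a NextSeq500 read both ends over 66 bp. The C57BL/6 libraries were sequencing batch 2 and the FVBxBALB/c libraries batch 1, so batch and background cannot be told apart. No knockout library was compared directly with a transgenic one in the planned tests.

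Per the labels, the authors made base calls with bcl2fastq and counted reads per gene with featureCounts on the mm10 genome. The deposited values are raw counts per gene with no normalization, 1 file per library. The aligner, the gene annotation, the counting settings and the software versions are not given in the sources used here. Each file held 27179 rows, of which 848 named no gene. The 26331 named genes were analysed, and the unnamed rows entered only a separate check. Gene positions on mm10 were taken from reference annotations through the Entrez identifiers, of which 25275 of 26331 matched. The files of both C57BL/6 replicates 5 at E15.5 carry a column name for E12.5 replicate 2, and the label of the knockout replicate 5 gives its tissue as dorsal telencephalon. Both libraries lay with the other E15.5 libraries on the first principal component, at 48.8 and 49.3, where the E12.5 libraries lay between -99.45 and -51.3, and they were analysed as E15.5.

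Total counts ranged from 10424813 to 49699656 per library. In each background, genes were kept by filterByExpr in edgeR (minimum count 10, minimum total 15), which left 16118 genes in C57BL/6 and 15556 in FVBxBALB/c. Counts were scaled by the trimmed mean of M values, and 1 quasi-likelihood negative binomial model per background, with a mean for each of its 4 groups and robust estimation, gave F tests with 12 residual degrees of freedom. The biological coefficient of variation was 0.162 in C57BL/6 and 0.188 in FVBxBALB/c. Every p for a gene is 2-sided. It was adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called changed at an adjusted p below 0.05. CPM values, counts scaled to the library total times its scaling factor, are given as mean ± SD, log2 fold changes with their standard error (SE), and intervals at 95%. By edgeR the SE is the absolute log2 fold change divided by the square root of F. It is worked back from the test and is not a separate estimate of the model. The intervals of fold changes cover counting error and the spread between libraries that the model fits. The interval of the ratio of Dupd1 to Kat6b counts and the floors cover counting error of the counts alone, and reads without molecular identifiers are not independent molecules.

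The comparisons were labelled knockout against wild type at each age, Tg(Kat6b) against wild type at each age, the difference of each genotype effect between the ages, and E15.5 against E12.5 in wild type of each background. A set of 29 gene lists was fixed before the data were examined, as were the groups, the tests and the rule for named genes; lists with fewer than 3 tested members were left out, which removed the HOX list. A list was tested with fry in limma, whose directional p asks whether its members move, on balance, one way, and whose mixed p asks whether they change in either direction. The p was adjusted over the 28 tested lists of a comparison. The alternative test was camera with an estimated correlation between members, and values given with an estimated correlation are from it. Camera asks whether the members move more than the other genes. By contrast, fry asks about the members alone and also allows for their correlation. A difference between both p values therefore does not measure the correlation alone. For lists, the count of members past the threshold over all genes is given beside the count adjusted over the list alone. The rule named Kat6b in every library, up to 10 higher and 10 lower called genes of each genotype comparison, up to 4 members of each list with the smallest adjusted p, and the 5 genes with the smallest p where fewer than 5 passed. Genes named with a change over age, and the genes named in the comparison of both genotypes, were chosen after their values were seen.

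Knockout and Tg(Kat6b) effects were compared by the overlap of genes at an unadjusted p under 0.05 in both, with Fisher's exact test, and by the correlation of log2 fold changes across genes, with an exact 2-sided permutation of the transgenic and wild-type labels. They were also compared by testing the 100 genes with the smallest p in each direction of one comparison in the other with fry, adjusted over 8 sets, because fewer than 10 genes were called in each. The 200 genes with the smallest p in each direction of the age change were tested in the genotype comparisons of the other background.

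The tests were tested on simulated data made from these libraries before they were read. Of 67 genes changed 2-fold, edgeR called 44 in the knockout comparison at E12.5, 56 at E15.5 and 48 in each transgenic comparison. Of 67 genes changed 1.5-fold it called 23, 42, 25 and 25. Lists of 17 genes were simulated too, 14 with every member shifted by -0.2 (log2) and 14 unshifted. All 14 shifted lists were called by fry in every genotype comparison, and of 14 unshifted lists it called 0, 3, 1 and 0. The simulated genes were drawn independently of one another. These calls therefore do not give the power or error of the lists in the real libraries, whose members may be correlated.

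The alternatives were DESeq2 with its own size factors and Wald test, those size factors within edgeR, limma-voom with sample quality weights, no filter, a filter at CPM above 1, robust estimation off, Y-linked expression as a covariate, the replicate number or the litter as a block, a fit of only the groups compared, a fit of all 32 libraries, and each library left out in turn. Alternatives chosen after seeing the data were the removal of ribosomal RNA genes, 1 surrogate variable, a covariate from the median level of non-cortical markers, the removal of both replicates 5, the removal of knockout replicates 3 and 4 at E15.5, and the lists without Kat6b and Dupd1. In C57BL/6 the labels give the same litter for both genotypes under each replicate number; at E15.5 each number is a litter of its own, and at E12.5 replicates 3 and 4 of both genotypes share 1 litter, so 2 libraries per genotype are littermates there. The correlation of residuals between the libraries that share a number ranged from -0.361 to 0.392 over the 3 pairs at E12.5 and from -0.112 to 0.389 over the 5 pairs at E15.5, and the model without a replicate block, chosen before, was run beside a replicate block and a litter block. Both blocks were set within each age, so they are the same at E15.5 and differ only at E12.5, whose libraries share the model. With either block the count of genes changed in the knockout at E12.5 was 0 in place of 1. No litters are given for FVBxBALB/c in the sources used here. Other splits of the same libraries were counted for each comparison. The software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, sva 3.50.0, Python 3.11.15 and matplotlib 3.10.9.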

Results

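RNA was counted per gene in 32 libraries of the mouse dorsal telencephalon at embryonic day E12.5 and of the cortex at E15.5. In C57BL/6 embryos, labelled Kat6b knockout and wild type had 3 libraries each at E12.5 and 5 each at E15.5. In mixed FVBxBALB/c embryos, Tg(Kat6b), a transgene that carries Kat6b, and wild type had 4 libraries each at both ages. Total counts per library at E12.5 were 18039586 to 43095686 in C57BL/6 wild type, 22952251 to 29148913 in the labelled knockout, 15760378 to 49699656 in FVBxBALB/c wild type and 22123762 to 39694868 in Tg(Kat6b). At E15.5 they were 11182987 to 38566194, 14920689 to 43362924, 10424813 to 22396130 and 10987750 to 19043161 in the same order. Age separated the libraries on the first principal component, which held 67% of the variance in C57BL/6 and 63% in FVBxBALB/c. Ribosomal RNA took 19.52% of the counts in labelled knockout replicate 3 at E15.5 and at most 0.729% in every other library.

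Kat6b encodes a lysine acetyltransferase of the MYST family that acts on histones, and its transcript was abundant in all 8 groups. In wild type it stood at 171 ± 20.8 CPM (counts scaled to the effective library size; mean ± SD, n = 3) at E12.5 and 174 ± 17.9 (n = 5) at E15.5 in C57BL/6, and at 175 ± 20.2 and 181 ± 32.4 (n = 4 each) in FVBxBALB/c. The gene (Entrez 54169) lies on mm10 chromosome 14 from 21499216 to 21672478. In the labelled knockout the Kat6b level was 153 ± 34.9 CPM (n = 3) at E12.5 and 178 ± 14.6 (n = 5) at E15.5. The ratio to wild type was 0.896 (95% interval 0.731 to 1.10, adjusted p = 0.918 by edgeR) at E12.5 and 1.03 (0.877 to 1.20, adjusted p = 1) at E15.5. The counts are summed over the whole gene, so they do not check the labelled genotype of these embryos. In Tg(Kat6b) tissue Kat6b rose to 541 ± 54.0 CPM at E12.5 and 654 ± 81.9 at E15.5 (n = 4 each), above every wild-type library. These were 3.09-fold (2.56 to 3.73, adjusted p = 1.03e-05) and 3.62-fold (2.99 to 4.38, adjusted p = 1.64e-06) the wild-type level.

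**Figure D1:**
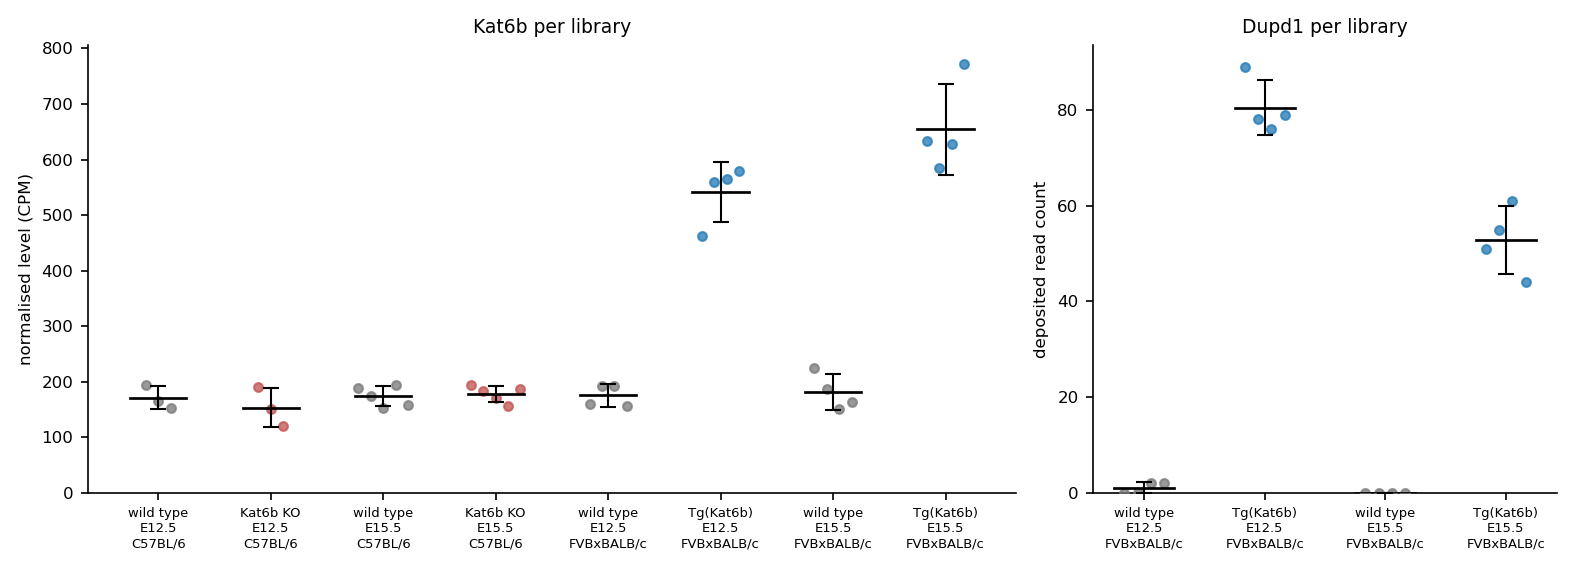
Kat6b in CPM in each library of the 8 groups and Dupd1 in deposited counts in each library of the 4 FVBxBALB/c groups; points are libraries, and lines give the mean and SD. Kat6b averaged 541 and 654 CPM in Tg(Kat6b) and 153 to 181 in the other groups, and Dupd1 had 44 to 89 counts per Tg(Kat6b) library and 0 to 2 per wild-type library.

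The labelled knockout was compared with wild-type dorsal telencephalon at E12.5 to find the genes that differ with the labelled genotype at the start of cortical neurogenesis. Of 16118 genes, 1 passed, and it fell: Stac, which encodes an adaptor protein with an SH3 domain. Stac (Entrez 20840, chromosome 9, 111561437 to 111690588) stood at 1.98 ± 0.324 CPM in the labelled knockout and 5.09 ± 0.0118 in wild type (n = 3 each). Its log2 fold change was -1.37 (SE 0.177, adjusted p = 0.0102), and it was lower in 3 of 3 libraries. At an unadjusted p under 0.05 there were 842 genes, where chance gives 806. DESeq2 called 5 genes and limma-voom 1. The 4 next genes by p did not pass. They were Plcxd2 (log2 fold change -0.54, SE 0.0935, adjusted p = 0.186), the chemokine gene Cxcl14 (1.27, SE 0.274), the zinc finger gene Tshz1 (-0.37, SE 0.0808) and AI504432 (-0.59), the last 3 each with an adjusted p of 0.867. Without labelled knockout replicate 3 Cxcl14 was at 0.78.

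None of the 28 gene lists passed at E12.5, and 0 members passed over all genes. Adjusted over the list alone, 1 apical progenitor gene (Lhx2) and 1 sex-linked gene (Xist) passed; wild-type replicate 4 was the 1 library of the comparison with Xist expression of a female. In the SOX family, transcription factors that keep progenitors or direct neuronal fate, 16 of 17 members had a log2 fold change below 0 (median -0.21, adjusted p = 0.13). Examples are Sox21 (-0.33, SE 0.124), Sox6 (-0.30, SE 0.127) and Sox5 (-0.31, SE 0.143), while Sox10 (0.78, SE 0.288) was the member above 0. Among apical progenitor genes, 14 of 23 lay below 0 (median -0.13, adjusted p = 0.677), with Lhx2, a LIM homeobox regulator of cortical identity, at -0.55 (SE 0.149; adjusted over the list alone, adjusted p = 0.0463). The neurogenic regulator Pax6 was at -0.22 (SE 0.0873) and the Notch effector Hes1 at -0.28 (SE 0.121). Of the intermediate progenitor genes 13 of 18 lay below 0 (median -0.16, adjusted p = 0.677), among them the proneural factor Neurog2 (-0.27, SE 0.0987) and the chromatin remodeller Chd7 (-0.31, SE 0.126). Leaving out 1 library moved several of these. Without wild-type replicate 1, Sox6 was at -0.17, Hes1 at -0.175, Pax6 at -0.09 and Chd7 at -0.08. Sox21 was at -0.50 and Sox10 at 0.51 without labelled knockout replicates 1 and 3, and Hes1 at -0.15 without replicate 4.

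Area patterning genes lay below 0 in 17 of 23 cases at E12.5 (median -0.13, adjusted p = 0.325), with the cortical homeobox gene Emx1 at -0.58 (SE 0.260) and Sp8 at -0.36 (SE 0.144). Deep-layer neuron genes did so in 14 of 18 (median -0.14, adjusted p = 0.420), with Nfia at -0.42 (SE 0.159) and Zfpm2 at -0.28 (SE 0.109). Upper-layer genes had a median of -0.14, a mean of 0.03 and an adjusted p of 0.715, with the homeobox gene Cux1 at -0.20 (SE 0.0590) and the POU factor Pou3f3 at -0.31 (SE 0.126). The neuronal bHLH genes Neurod6 and Neurod2 were at -0.81 (SE 0.241) and -0.60 (SE 0.245), in a pan-neuronal list whose median of 0.02 and mean of -0.04 differ in sign (adjusted p = 0.844). The semaphorin coreceptor Plxna4 was at -0.51 (SE 0.156) and the ephrin receptor Epha5 at -0.40 (SE 0.126), in an axon guidance list with 21 of 32 below 0 (adjusted p = 0.677). The Wnt receptor Fzd8 was at -0.35 (SE 0.148) and the glial gene Gpr17 at 0.78 (SE 0.243). Cell cycle genes lay below 0 in 28 of 30 (median -0.12, adjusted p = 0.715) and ribosomal protein genes above 0 in 46 of 50 (median 0.13, adjusted p = 0.677). All members named here had an adjusted p of 0.881 over all genes. Without labelled knockout replicate 1, Emx1 was at -0.99, Sp8 at -0.60 and Fzd8 at -0.59. Emx1 was at -0.35 without replicate 4 and Sp8 at -0.21 without replicate 3, and Pou3f3 at -0.20 and Neurod2 at -0.39 without wild-type replicate 3.

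Other cell types also differed between the libraries at E12.5. Meningeal and mesenchymal markers lay above 0 in 17 of 18 (median 0.63, adjusted p = 0.795), among them Mgp, a matrix protein gene of mesenchyme, at 2.52 (SE 1.02), or at 0.45 without labelled knockout replicate 3. Erythroid markers lay below 0 in 11 of 11 (median -0.32, adjusted p = 0.677), and ventral telencephalic markers above 0 in 19 of 22 (median 0.13, adjusted p = 0.715). The median deviation of the meningeal markers from the mean of the libraries of this age ranged from -1.07 to 1.39 (log2) within the labelled knockout and from -0.751 to 0.702 within wild type. The call on Stac was lost with a replicate block (adjusted p = 0.149), a litter block (0.0617), the Y-linked covariate (0.0664) and a fit of only these 6 libraries (1.00), over a range of 2.29e-08 to 1 in 16 settings. It was also lost without wild-type replicate 3 (0.0636) or 4 (0.0611) and without labelled knockout replicate 3 (0.155) or 4 (0.138); without wild-type replicate 1, and without labelled knockout replicate 1, 2 genes passed.

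The same comparison in the E15.5 cortex asked which genes differ when upper-layer neurons are being made. The SOX family list fell as a group (adjusted p = 0.0362 by fry), a call that ended with a litter block or a replicate block, and no single gene passed. The genes with the smallest p included Nr2e1 (TLX), a nuclear receptor of neural stem cells, and Otx1, a homeobox gene of cortical progenitors and deep-layer neurons. Nr2e1 (Entrez 21907, chromosome 10, 42561963 to 42583590) stood at 66.9 ± 5.69 CPM in the labelled knockout and 92.8 ± 8.16 in wild type, a log2 fold change of -0.47 (SE 0.0807, adjusted p = 0.315). Otx1 (Entrez 18423, chromosome 11, 21994764 to 22001651) stood at 20.1 ± 0.724 and 29.9 ± 3.39 CPM, a log2 fold change of -0.57 (SE 0.109, adjusted p = 0.356). For both genes all 5 labelled knockout libraries lay below all 5 wild-type libraries. The cadherin-related gene Cdhr1 (1.68, SE 0.322), the stress-response gene Sesn2 (-0.61, SE 0.121) and A930004D18Rik (-0.45, SE 0.0897) followed, each with an adjusted p of 0.356. By edgeR 0 of 16118 genes passed, with 456 at an unadjusted p under 0.05 where chance gives 806. DESeq2 called 7 genes, Nr2e1 and Otx1 among them, but in simulated data 24 of its 154 calls here were unchanged genes. By limma-voom 1 gene passed, Nr2e1 (adjusted p = 0.0372). Nr2e1 also passed with a litter block (adjusted p = 0.0302), in a fit of only these 10 libraries (0.0375) and in a fit of all 32 libraries (0.0339), over a range of 0.000619 to 1 in 16 settings.

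In the SOX family at E15.5, 15 of 17 members lay below 0 with a median log2 fold change of -0.20 (adjusted p = 0.00937 with an estimated correlation). Of its 17 members 0 passed over all genes and 1, Sox21, passed adjusted over the list alone (adjusted p = 0.00923). Sox21, a progenitor factor, stood at 45.7 ± 4.90 CPM in the labelled knockout and 61.0 ± 4.01 in wild type (n = 5 each), a log2 fold change of -0.42 (SE 0.0975). Sox1 (-0.24, SE 0.0863), Sox13 (-0.23, SE 0.0846) and Sox2 (-0.21, SE 0.0838), the first and last of them factors of neural stem cells, had an adjusted p of 1 over all genes. Per library, the median deviation of the SOX genes ran from -0.169 to -0.0501 in the labelled knockout and from 0.0321 to 0.112 in wild type. The list was lost in 7 of 13 settings, over a range of 0.00937 to 0.305. Among these were a replicate block (adjusted p = 0.305) and a litter block (0.252), which are the same block at E15.5. Another was the removal of labelled knockout replicates 3 and 4 (0.137). The others were the Y-linked covariate, the non-cortical covariate, 1 surrogate variable and the removal of both replicates 5. With 1 library left out its adjusted p was 0.0292 without wild-type replicate 3 and up to 0.122 without any of the other 9 libraries, each of which ended the call.

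No other list passed its directional test in the E15.5 labelled knockout, and 0 members of any list passed over all genes. The list of CDK inhibitors and p53 targets had a mixed adjusted p of 0.0270 and a directional one of 0.261. Its members Sesn2 (-0.61; adjusted over the list alone, adjusted p = 0.00183) and Cdkn1b, an inhibitor of cyclin-dependent kinases (-0.20, SE 0.0703, or -0.10 without labelled knockout replicates 3 and 4), lay below 0. Of the upper-layer genes 12 of 18 lay below 0 (median -0.09, adjusted p = 0.555). Pou3f3 passed adjusted over the list alone (-0.39, SE 0.0980, adjusted p = 0.0175), and Cux1 was at -0.12 (SE 0.0458). Apical progenitor genes had a median of 0.00334, a mean of -0.0172, which differ in sign, and an adjusted p of 0.716, with Lhx2 at -0.40 (SE 0.116), Pax6 at -0.21 (SE 0.0686) and Hes1 at -0.28 (SE 0.0978). Of the intermediate progenitor genes 14 of 18 lay below 0 (median -0.12, adjusted p = 0.501), with the Notch ligand Dll1 at -0.18 (SE 0.0683) and Insm1 at -0.26 (SE 0.106). The area patterning gene Nr2f1 was at -0.23 (SE 0.0951) in a list with 15 of 23 below 0 (adjusted p = 0.555). The Wnt receptors Fzd1 and Fzd8 were at -0.22 (SE 0.0843) and -0.30 (SE 0.118) in a list with 12 of 22 below 0 (adjusted p = 0.716). Beta protocadherins, adhesion genes of neurons, lay above 0 in 18 of 21 (median 0.11, adjusted p = 0.501), among them Pcdhb10 (0.57, SE 0.237) and Pcdhb6 (0.65, SE 0.258, or 0.26 without labelled knockout replicates 3 and 4). Immediate early genes lay below 0 in 16 of 18 (median -0.13, adjusted p = 0.469), with Jun at -0.21 (SE 0.0634). Without labelled knockout replicates 3 and 4, Insm1 was at -0.15, Nr2f1 at -0.36 and Fzd8 at -0.17.

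Several groups at E15.5 moved with labelled knockout replicates 3 and 4, which stood apart on the second principal component at -44.1 and -35.2 (other E15.5 C57BL/6 libraries -17.5 to 29.3). Meningeal and mesenchymal markers lay above 0 in 17 of 18 (median 0.85, adjusted p = 0.716). Their deviation was 1.72 and 1.71 in these libraries and -1.01 to -0.309 in the other labelled knockout libraries. The collagen gene Col3a1 had 70.6 and 67.3 CPM there and 4.55 to 33.5 elsewhere, for a log2 fold change of 1.29 (SE 0.871) that became -0.867 without both, 0.77 and 0.78 without either alone and 2.06 without wild-type replicate 3. Hem and choroid plexus genes lay above 0 in 20 of 20 (median 0.48, adjusted p = 0.501), with the signalling genes Wnt2b (0.50, SE 0.218) and Bmp6 (0.86, SE 0.382), and their deviation was 0.787 and 0.845 in the same libraries. Cajal-Retzius genes lay above 0 in 13 of 14 (median 0.26, adjusted p = 0.501), with the extracellular glycoprotein gene Reln at 0.42 (SE 0.185) and the calcium-binding protein gene Calb2 at 0.54 (SE 0.252), and deviated by 0.548 and 0.531. Cell cycle genes lay below 0 in 28 of 30 (median -0.14, adjusted p = 0.501), with the mitotic kinase Aurka at -0.24 (SE 0.0940) and Foxm1 at -0.24 (SE 0.0974), and deviated by -0.26 and -0.243 against -0.00189 to 0.149 in the other 8 libraries. Markers of diencephalon, midbrain and hindbrain had a median of 0.17 and a mean of -0.22, which differ in sign (adjusted p = 0.97), and deviated by 1.85 and 1.69. Without both libraries Bmp6 was at 0.43, Calb2 at 0.10, Aurka at -0.14 and Foxm1 at -0.10, and 0 genes passed at E15.5; Reln was at 0.20 without labelled knockout replicate 2.

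**Figure D2:**
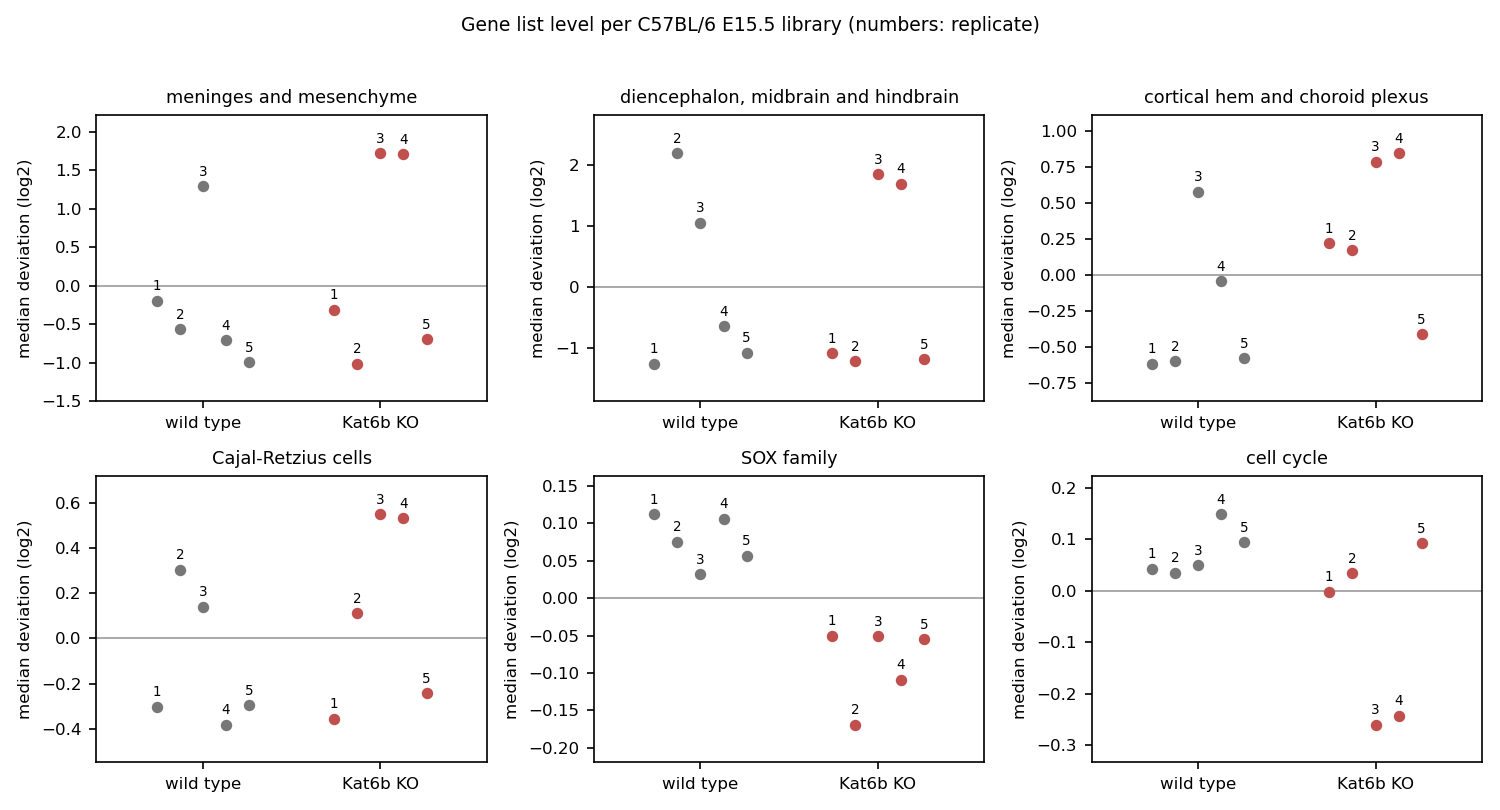
Median deviation (log2, from the mean of the C57BL/6 libraries at E15.5) of the genes of 6 lists in each library; points carry the replicate number. SOX family genes lay at -0.169 to -0.0501 in the 5 labelled knockout libraries and at 0.0321 to 0.112 in the 5 wild-type libraries, and labelled knockout replicates 3 and 4 had meningeal deviations of 1.72 and 1.71.

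Tg(Kat6b) was compared with wild-type dorsal telencephalon at E12.5 to find the genes that respond to extra Kat6b. Kat6b itself rose 3.09-fold, and the neighbouring gene Dupd1, which encodes a dual specificity phosphatase, rose from near absence. Dupd1 (Entrez 435391) lies on chromosome 14 from 21676565 to 21714576, 4087 bp beyond the end of Kat6b. It had 76 to 89 counts in each Tg(Kat6b) library (2.71 ± 0.508 CPM, n = 4) and 0 to 2 in each wild-type library (4 counts in all; adjusted p = 1.17e-05). These were the 2 genes of 15556 that passed, and 1039 genes had an unadjusted p under 0.05, where chance gives 778. DESeq2 called 6 genes and limma-voom with quality weights 832. In that fit wild-type replicate 4 had a weight of 0.152 and Tg(Kat6b) replicate 1 a weight of 0.272. Tlr1, an innate immune receptor gene (-2.22, SE 0.448, adjusted p = 0.566), AW209491 (0.48, SE 0.0978, 0.566) and Gcn1l1, which acts in the response to amino acid shortage (-0.47, SE 0.0976, 0.574), came next and did not pass.

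Of 19 tested genes within 1 Mb of Kat6b, only Dupd1 passed at E12.5, and the median log2 fold change of the other 18 was -0.0197 (SD 0.222). The list of Kat6b neighbours passed (median 0.03, adjusted p = 0.00684, and adjusted p = 0.125 with an estimated correlation), and of its 10 members 1, Dupd1, passed over all genes and adjusted over the list alone. Without Kat6b and Dupd1 in the lists 0 lists passed, and 0 passed with a replicate block; without Tg(Kat6b) replicate 4, 0 lists passed, and without replicate 1, 2 did, with CDK inhibitors and p53 targets added (adjusted p = 0.00780). In the list of MYST acetyltransferases and their BRPF partners 1 of 14, Kat6b, passed over all genes and adjusted over the list alone. Its median of -0.01 and mean of 0.09 differ in sign (adjusted p = 0.365).

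In all other lists of the E12.5 transgenic comparison 0 members passed over all genes, and 1 passed adjusted over the list alone, the transcription factor gene Gata2 (-1.54, SE 0.436, adjusted p = 0.0498). Gata2 belongs to the markers of diencephalon, midbrain and hindbrain, of which 16 of 18 lay below 0 (median -1.01, adjusted p = 0.509), with the neural crest and dorsal neural tube factor Pax3 at -1.90 (SE 0.604). Their deviation per library ran from -1.89 to 0.425 in Tg(Kat6b) and from -0.805 to 1.71 in wild type. Markers of meninges, vessels, microglia and blood cells lay below 0 as well. Meningeal and mesenchymal genes did so in 17 of 18 (median -0.69, adjusted p = 0.706), with the retinoic acid synthesis gene Aldh1a2 at -2.77 (SE 0.820). Endothelial and pericyte genes did so in 17 of 18 (median -0.22, adjusted p = 0.365), with Vtn (-0.58, SE 0.199), the pericyte receptor Pdgfrb (-0.54, SE 0.203) and the VEGF receptor Flt1 (-0.29, SE 0.112). Microglial genes did so in 13 of 17 (median -0.33, adjusted p = 0.365), with the receptors Csf1r (-0.41, SE 0.147) and Cx3cr1 (-0.33, SE 0.125). Erythroid genes did so in 10 of 11 (median -0.59, adjusted p = 0.706). Wild-type replicate 4 had the highest deviation of the 8 libraries in meningeal (1.69), endothelial (0.382) and erythroid (1.57) markers. Without it Aldh1a2 was at -0.89, Vtn at -0.35, Pdgfrb at -0.32 and Csf1r at -0.26, and Pax3 was at -1.23 without wild-type replicate 1.

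Other lists did not pass at E12.5 in Tg(Kat6b) either. The radial glial lipid-binding protein genes Fabp7 (0.28, SE 0.0831) and Dbi (0.42, SE 0.151) lay above 0 in a list of apical progenitor genes with a median of 0.01 and a mean of -0.00866, which differ in sign (adjusted p = 0.719). Notch pathway genes lay below 0 in 16 of 20 (median -0.10, adjusted p = 0.408), with the receptor Notch2 at -0.34 (SE 0.123) and the ligand Jag1 at -0.24 (SE 0.107). CDK inhibitors and p53 targets lay above 0 in 16 of 19 (median 0.13, adjusted p = 0.365), with Ccng1 at 0.31 (SE 0.127). The ligand Wnt7b was at 0.31 (SE 0.108), the ephrin receptor Epha7 at -0.26 (SE 0.0931), Cdh10 at -0.49 (SE 0.153) and the proteoglycan gene Cspg4 of oligodendrocyte precursors and pericytes at -0.77 (SE 0.240). In the SOX family 11 of 17 lay below 0 (median -0.07, adjusted p = 0.773), with Sox13 at -0.26 (SE 0.103) and Sox9 at -0.18 (SE 0.0816). Ribosomal protein genes lay above 0 in 40 of 50 (median 0.22, adjusted p = 0.572), with Rplp0 at 0.86 (SE 0.253) and Rpl15 at 0.29 (SE 0.0935). The genes named here had adjusted p values of 0.724 to 0.743 over all genes. Ccng1 was at 0.19 without Tg(Kat6b) replicate 4 and Rpl15 at 0.19 without replicate 2.

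At E15.5 the comparison of Tg(Kat6b) with wild type asked the same of the cortex. Again Kat6b (3.62-fold) and Dupd1 rose, and they were the only 2 of 15556 genes that passed. Dupd1 had 44 to 61 counts in each Tg(Kat6b) library (4.05 ± 0.803 CPM, n = 4) and 0 in each wild-type library (adjusted p = 1.52e-05). Against a floor of 3 counts per wild-type library it was at least 17.5-fold higher. Among the 18 other tested genes within 1 Mb the median log2 fold change was 0.016 (SD 0.172), and none of them passed. At an unadjusted p under 0.05 there were 346 genes, where chance gives 778, and DESeq2 called 7 and limma-voom 3. Fut10, a fucosyltransferase gene (Entrez 171167, chromosome 8, 31187313 to 31265284), did not pass. It stood at 14.9 ± 0.901 CPM in Tg(Kat6b) and 8.02 ± 0.269 in wild type (n = 4 each), a log2 fold change of 0.89 (SE 0.164, adjusted p = 0.242), with 4 of 4 Tg(Kat6b) libraries above all wild-type libraries. In a fit of only these 8 libraries, and in a fit of all 32, 4 genes passed; Fut10 passed in both (adjusted p = 0.00886 and 0.0242), with DESeq2 (0.00182) and with a replicate block (0.0337), over a range of 0.00182 to 0.666 in 13 settings. Platr25 (3.78, SE 0.804), the thyrotropin-releasing hormone receptor gene Trhr (-1.47, SE 0.323) and Nr2e1 (0.40, SE 0.0910) followed, each with an adjusted p of 0.907. In wild type at E15.5 Fut10 stood at 15.91 CPM or more in C57BL/6 and at 8.388 or less in FVBxBALB/c. Its level in the Tg(Kat6b) libraries was 13.81 to 16.01 CPM. Whether the mixed background takes part in the Fut10 difference was not tested.

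The MYST and BRPF list, which holds Kat6b, passed at E15.5 (median 0.10, 11 of 14 above 0, adjusted p = 0.00739, and adjusted p = 0.00428 with an estimated correlation). Of its 14 members 1, Kat6b, passed over all genes and adjusted over the list alone, and the BRPF family scaffold gene Brd1 was at 0.18 (SE 0.0812, adjusted p = 1). The Kat6b neighbours passed (median 0.04, adjusted p = 0.00654, and 0.00428 with an estimated correlation) with 1 of 10 members past the threshold both ways, Dupd1. Without Kat6b and Dupd1 in the lists 0 lists passed, so both calls rest on these genes and do not show a rise of either group.

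The remaining lists did not pass in the E15.5 transgenic cortex, and 0 of their members passed over all genes. Progenitor and proliferation genes lay mostly above 0. Intermediate progenitor genes did so in 15 of 18 (median 0.12, adjusted p = 0.169), with Dll1 at 0.18 (SE 0.0966). Apical progenitor genes did so in 16 of 23 (median 0.12, adjusted p = 0.296), with Pax6 at 0.25 (SE 0.122, or 0.14 without Tg(Kat6b) replicate 4). Cell cycle genes did so in 27 of 30 (median 0.14, adjusted p = 0.489), with the ribonucleotide reductase subunit Rrm2 at 0.26 (SE 0.0991), the replication licensing factor Mcm2 at 0.23 (SE 0.0968) and the mitotic kinase Plk1 at 0.19 (SE 0.0913). Wnt pathway genes did so in 18 of 22 (median 0.10, adjusted p = 0.500), with Fzd8 at 0.27 (SE 0.102) and Fzd1 at 0.21 (SE 0.104). Notch pathway genes did so in 15 of 20 (median 0.08, adjusted p = 0.489), with the coactivator gene Maml2 at 0.22 (SE 0.0922). SOX genes did so in 14 of 17, with a median of 0.10 and a mean of -0.04 that differ in sign (adjusted p = 0.376). They included Sox9 (0.27, SE 0.0829), Sox21 (0.28, SE 0.124) and Sox2 (0.18, SE 0.0824). Hypoxia and glycolysis genes lay above 0 in 16 of 19 (median 0.10, adjusted p = 0.840), with the hexokinase gene Hk2 at 0.38 (SE 0.145). The deep-layer factor Tbr1 was at 0.25 (SE 0.126, or 0.15 without Tg(Kat6b) replicate 4) and Pou3f3 at 0.14 (SE 0.0795, or 0.09 without wild-type replicate 2), in layer lists with medians of 0.00470 and -0.02 (adjusted p = 0.954 for both; the mean of the deep-layer list was -0.00643).

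Non-neuronal genes in the E15.5 transgenic cortex lay mostly below 0. Oligodendrocyte and astrocyte genes did so in 13 of 15 (median -0.15, adjusted p = 0.489), with the astrocyte water channel gene Aqp4 at -0.91 (SE 0.273). Microglial genes did so in 12 of 17 (median -0.04, adjusted p = 0.867), with Aif1 at -0.72 (SE 0.332). Hem and choroid plexus genes did so in 12 of 20 (median -0.16, adjusted p = 0.954), with 1 member past the threshold adjusted over the list alone, Ttr (adjusted p = 0.0473), the choroid plexus gene for transthyretin. Ttr was at 428 CPM in wild-type replicate 3 and at most 2.81 in the other 7 libraries, and without that library its log2 fold change went from -7.10 to -1.41 and that of Aif1 to -0.44. Every gene named here had an adjusted p of 1 over all genes.

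**Figure D3:**
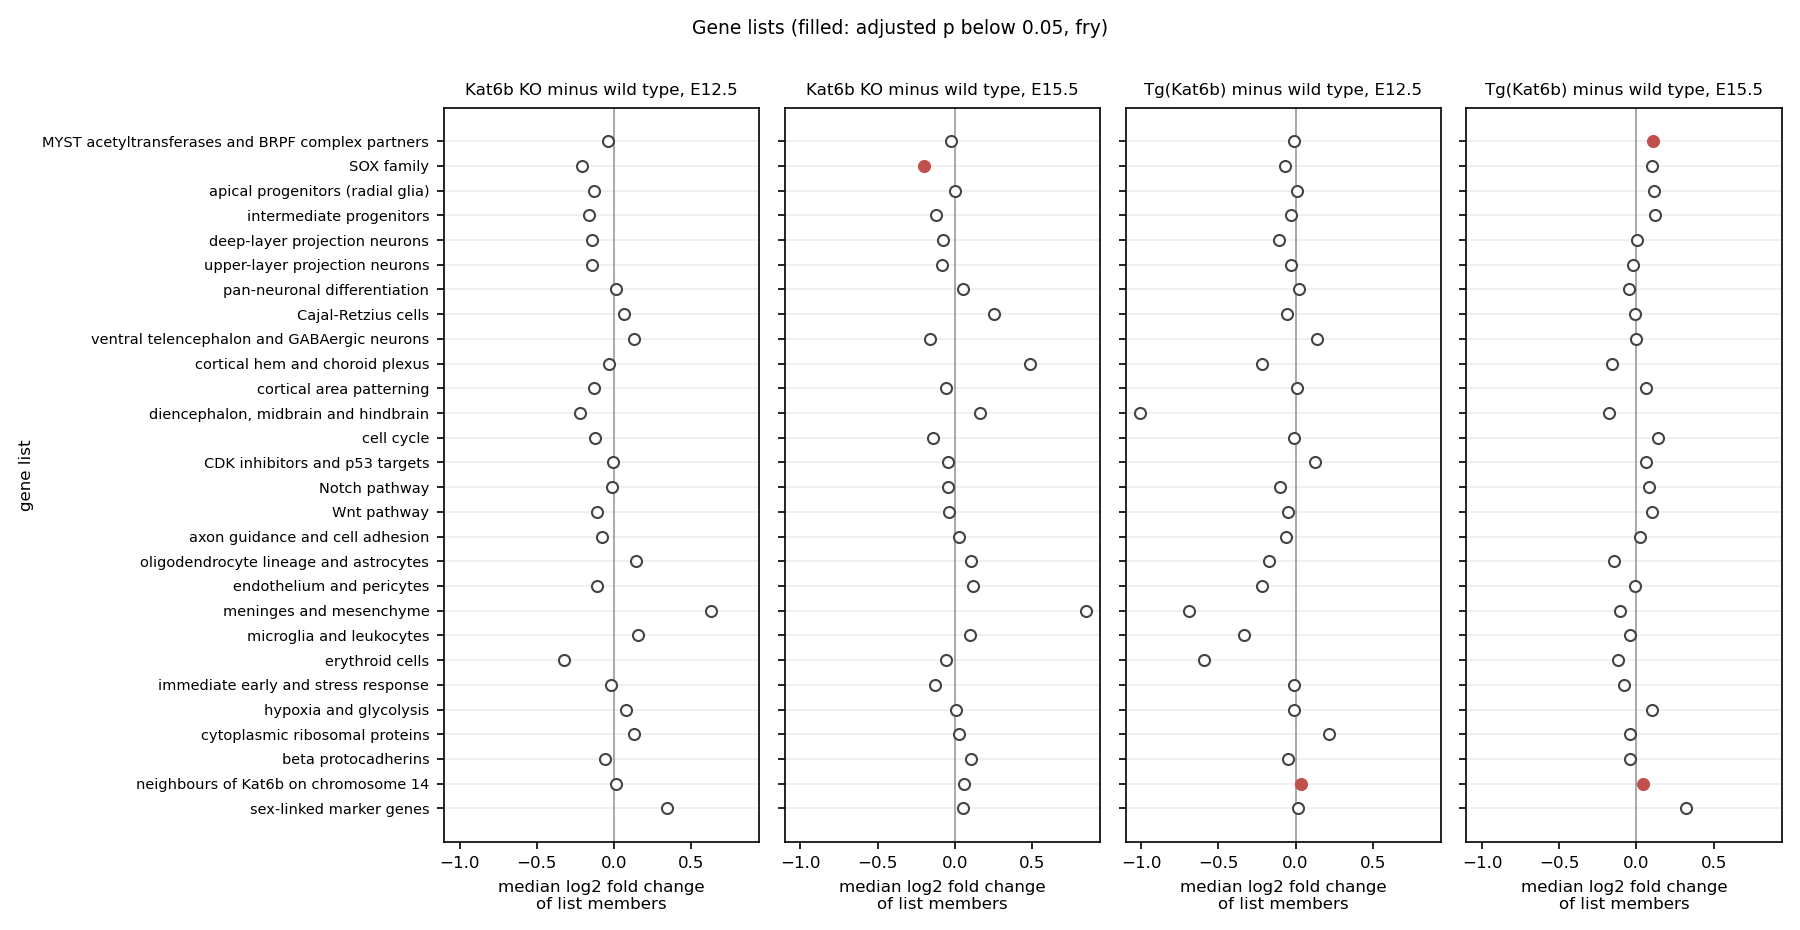
Median log2 fold change of 28 gene lists in the 4 genotype comparisons; filled points are lists with a directional adjusted p below 0.05. SOX genes in the labelled knockout at E15.5 had a median of -0.20, and the MYST list in Tg(Kat6b) at E15.5 had 0.10.

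The labelled knockout and Tg(Kat6b) were then compared to ask whether they move the same genes in opposite directions. At E15.5 they did for more genes than independence gives: 38 genes had an unadjusted p under 0.05 in both comparisons where 9.18 were expected, and 33 of them had opposite directions (4.58 expected; Fisher's exact p = 9.89e-14 for the overlap, which treats genes as independent). Lower in the labelled knockout and higher in Tg(Kat6b) were Nr2e1 (-0.47 and 0.40), Otx1 (-0.57 and 0.48), Sox21 (-0.42 and 0.28), Sox2 (-0.21 and 0.18), Fzd8 (-0.30 and 0.27), the hedgehog effector Gli2 (-0.26 and 0.29) and the radial glial regulator Prdm16 (-0.29 and 0.23). Bmp2, a secreted signal of the TGF-beta superfamily (0.97 and -0.97), and the Wnt inhibitor Wif1 (0.90 and -0.79) went the other way. Without labelled knockout replicates 3 and 4 the values there were -0.17 for Fzd8, -0.16 for Gli2 and 0.23 for Wif1. These genes were chosen after their values were seen, and 0 genes passed over all genes in both comparisons. In Tg(Kat6b) at E15.5, Otx1 stood at 44.2 ± 7.09 CPM against 31.6 ± 1.34 in wild type (n = 4 each, SE 0.121, adjusted p = 1), with 4 of 4 libraries above all of wild type, as for Nr2e1.

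The 5 genes that went the same way in both comparisons at E15.5, each above 0, were Rmrp (6.31 and 2.74), Rn7sk (4.68 and 1.72) and the histone genes Hist1h1e, Hist1h4d and Hist1h4h, whose RNAs carry no poly(A) tail. Each was highest in labelled knockout replicate 3 and in Tg(Kat6b) replicate 2, the E15.5 libraries of each background with the most ribosomal RNA (19.52% and 0.729%). Without these libraries Rmrp was at 0.30 and 1.63 and Rn7sk at 0.84 and 0.75. Without labelled knockout replicate 3, 23 genes had opposite directions and 1 the same.

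As sets, the 100 genes lowest by p in the labelled knockout at E15.5 rose in Tg(Kat6b), with 87 of 100 above 0 (median 0.14, adjusted p = 0.0348, and 0.0191 with an estimated correlation). The other sets did not pass by fry: genes higher in the labelled knockout (median -0.15 in Tg(Kat6b), adjusted p = 0.119, and 0.0449 with an estimated correlation), higher in Tg(Kat6b) (-0.10 in the labelled knockout, 0.0731 and 0.0362) and lower in Tg(Kat6b) (0.16, 0.0596 and 0.0362). In the same order these had adjusted p values of 0.0271, 0.0271 and 0.0103 with a litter block in C57BL/6 and 0.01005, 0.0249 and 0.01005 with a replicate block, over ranges of 0.01005 to 0.411, 0.0249 to 0.411 and 0.000364 to 0.445 in 11 settings, of which 3, 3 and 8 made the call. With 1 of the 32 libraries left out, the set higher in Tg(Kat6b) passed in 4 fits (0.0197 to 0.258), without labelled knockout replicate 1 of E12.5, or at E15.5 C57BL/6 wild-type replicate 3, FVBxBALB/c wild-type replicate 3 or Tg(Kat6b) replicate 4. The set lower in Tg(Kat6b) passed in 13 fits (0.0145 to 0.163). These were without labelled knockout replicate 1, any FVBxBALB/c wild-type library or Tg(Kat6b) replicate 2, 3 or 4 of E12.5, and at E15.5 without C57BL/6 wild-type replicate 3, labelled knockout replicate 5, FVBxBALB/c wild-type replicate 3 or Tg(Kat6b) replicate 2 or 4. The log2 fold changes of both comparisons correlated across 15447 genes, which are not independent replicates, with r = -0.188 and Spearman's rho = -0.296 (exact 2-sided permutation of the 8 transgenic libraries, 70 labelings, p = 0.114 for r). At E12.5 there was no excess: 50 genes overlapped where 54.0 were expected (exact p = 0.613), with 35 in opposite directions (28.1 expected), no set passed (adjusted p = 0.118 to 0.868), and r was -0.133 (rho = -0.138, exact permutation p = 0.229). The 35 became 61 without C57BL/6 wild-type replicate 3, 12 without labelled knockout replicate 3, and 68, 18 and 18 without Tg(Kat6b) replicates 1, 2 and 3. With 1 of the 32 libraries left out, the set higher in the labelled knockout at E12.5 passed by fry in 1 fit (adjusted p from 0.0319 to 0.953). The set of genes lower in the labelled knockout at E15.5 did not pass without labelled knockout replicates 3 and 4 (adjusted p = 0.517, with 14 genes opposite and r at -0.0327; range 0.0116 to 0.517 in 11 settings). Leaving out 1 library ended the call on this set in 13 cases: without wild-type replicate 3 (0.0705) or labelled knockout replicate 4 (0.0516) of E12.5, which share its model, and at E15.5 without C57BL/6 wild-type replicate 1 (0.0558) or 2 (0.235), labelled knockout replicate 2 (0.114), 3 (0.0586), 4 (0.0795) or 5 (0.0683), FVBxBALB/c wild-type replicate 1 (0.0788), 2 (0.105) or 4 (0.0717), and Tg(Kat6b) replicate 1 (0.133) or 3 (0.0864). Without Tg(Kat6b) replicate 1 the count of opposite genes at E15.5 was 17.

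**Figure D4:**
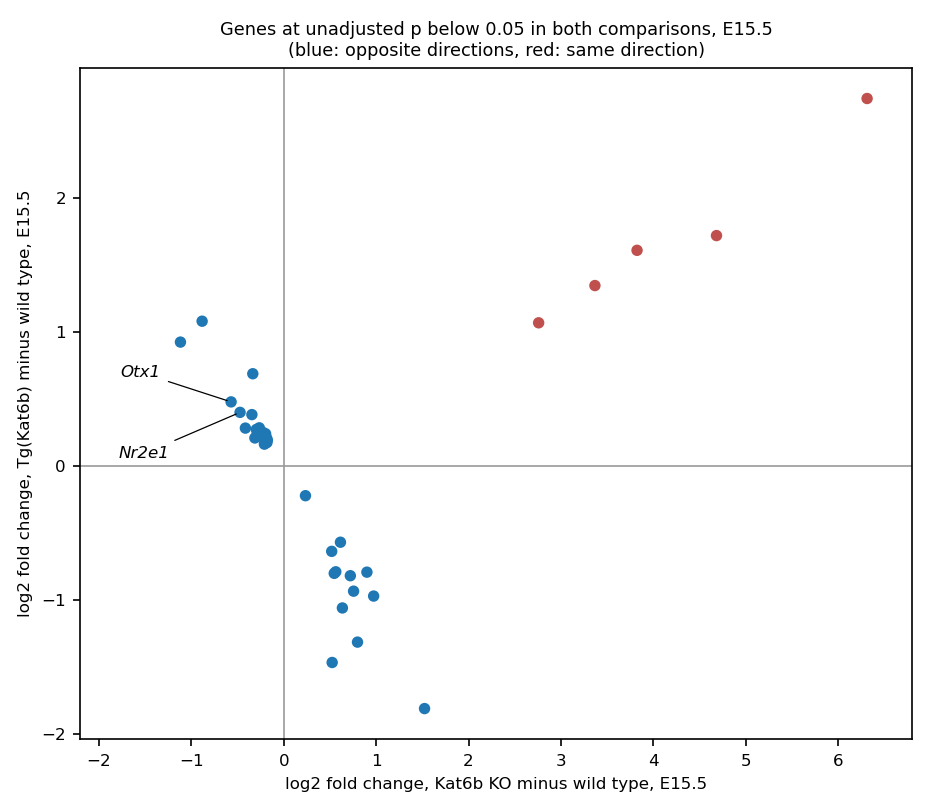
Log2 fold change in the labelled knockout (horizontal) against that in Tg(Kat6b) (vertical) for the 38 genes at an unadjusted p under 0.05 in both at E15.5; blue points have opposite directions and red points the same. Blue points number 33 and red points 5.

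**Figure D5:**
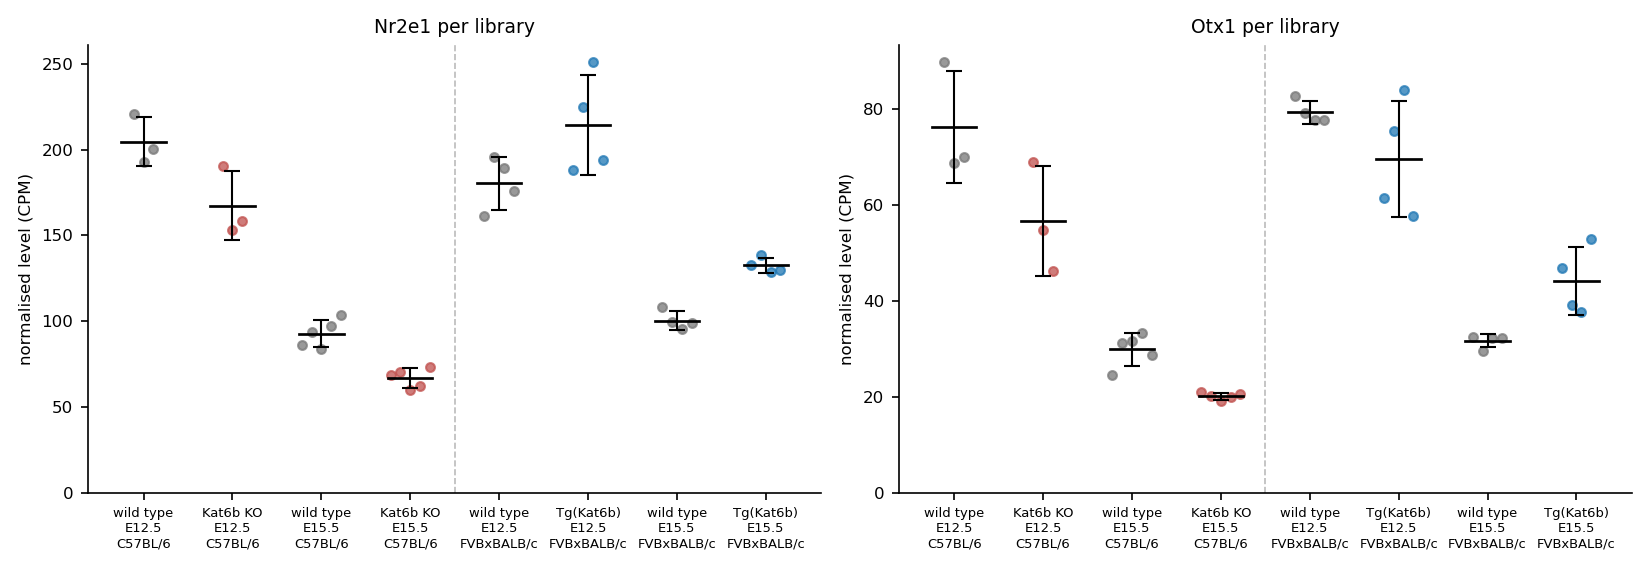
Nr2e1 and Otx1 in CPM in each library of the 8 groups, with mean and SD. At E15.5 Nr2e1 averaged 66.9 CPM in the labelled knockout and 92.8 in its wild type, and 132.5 in Tg(Kat6b) and 100.35 in its wild type.

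Whether each genotype effect differed between E12.5 and E15.5 was tested directly. By edgeR 0 genes passed for the labelled knockout (438 at an unadjusted p under 0.05, where chance gives 806) and 0 for Tg(Kat6b) (628, where chance gives 778). DESeq2 and limma-voom each called 1 gene in either case. For the labelled knockout both called Stac, whose log2 fold change was -1.37 at E12.5 and 0.05 (SE 0.134) at E15.5. Averaged over both ages, an added comparison, 0 genes passed in the labelled knockout (959 at an unadjusted p under 0.05) and 3 in Tg(Kat6b), Kat6b, Dupd1 and Fut10 (0.76, SE 0.112, adjusted p = 0.0186). With a litter block 2 genes passed in the labelled knockout, Nr2e1 (adjusted p = 0.0280) and Otx1 (0.0308).

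Wild-type tissue was compared between E15.5 and E12.5 to place the genotype effects against normal maturation, in which cortical progenitors give way to neurons. By the labels the dissected tissue changes with age, from dorsal telencephalon to cortex, so age and dissection cannot be told apart. In C57BL/6 4613 genes rose and 4544 fell, 9157 in all, and in FVBxBALB/c 3900 rose and 3898 fell, 7798 in all. Of 15448 genes tested in both, 6692 changed in both and 6687 of these in the same direction (r = 0.907 across genes). All 30 cell cycle genes fell in both backgrounds (median -1.21 in C57BL/6 and -1.02 in FVBxBALB/c, adjusted p = 8.43e-07 and 8.15e-07). Among them were Birc5 (-1.40, SE 0.0881, and -1.06, SE 0.125), which acts in chromosome segregation, and the spindle checkpoint kinase Bub1 (-1.49 and -1.19). Notch genes fell in 14 and 16 of 20 (median -0.71 in both; 1.23e-08 and 8.34e-07), with Hes5 at -1.48 and -1.07 and Notch3 at -1.43 and -1.81. Wnt genes fell in 15 and 16 of 22 (median -0.85 in both; 2.37e-06 and 1.75e-06), with Ccnd1 at -2.33 (SE 0.0872) and -2.17 (SE 0.129). Camera with an estimated correlation compares a list with the other genes, of which many also changed with age. Its adjusted p was 0.138 and 0.121 for cell cycle, 0.0280 and 0.121 for Notch and 0.195 and 0.121 for Wnt.

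Neuronal genes rose with age. Pan-neuronal genes rose in 23 and 22 of 25 (median 1.49 in C57BL/6 and 1.24 in FVBxBALB/c, adjusted p = 4.24e-06 and 1.45e-05), among them the synaptic vesicle gene Syn1 (1.61 and 1.39) and Neurod6 (2.62 and 3.17). Deep-layer genes rose in 14 and 13 of 18 (median 1.27 and 1.33; 4.79e-09 and 1.61e-07), with the transcriptional cofactor gene Ldb2 at 1.73 in both. Upper-layer genes rose in 14 and 15 of 18 (median 1.04 and 1.02; 7.63e-08 and 1.91e-07), with Mef2c at 2.52 and 2.60. Beta protocadherins rose in 20 and 15 of 21 (median 1.51 and 0.83; 8.43e-07 and 0.000266). Oligodendrocyte and astrocyte genes rose in 8 and 7 of 15 (median 0.99 and 0.52; 5.27e-05 and 8.79e-05), with the astrocyte enzyme gene Aldh1l1 at 3.96 and 3.56. With an estimated correlation the adjusted p was 0.0176 and 0.0822 for deep-layer, 0.0684 and 0.0822 for upper-layer, 0.206 and 0.259 for pan-neuronal, 0.206 and 0.472 for protocadherin and 0.342 and 0.400 for glial genes.

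Genes of neighbouring tissue and of blood cells were lower at the later age. The labelled tissue also differs there, so a change of dissection cannot be told apart from age. Hem and choroid plexus genes fell in 13 and 15 of 20 (median -1.84 in C57BL/6 and -2.02 in FVBxBALB/c, adjusted p = 0.000381 and 3.11e-05), with the signals Wnt8b at -3.33 and -3.23 and Rspo1 at -2.88 and -3.15. Meningeal genes fell in 12 and 17 of 18 (median -2.65 and -3.86; 0.00547 and 0.000615), with the transcription factor Foxc1 at -2.43 and -2.75. Erythroid genes fell in 9 and 7 of 11 (median -2.41 and -1.39; 1.27e-05 and 0.00258), with the embryonic globin Hbb-y at -7.34 and -6.74. With an estimated correlation these had an adjusted p of 0.382 and 0.259, 0.607 and 0.400, and 0.206 and 0.472. In FVBxBALB/c the count of age-changed genes was 3815 with a replicate block. A shift of the genotype comparisons along this axis was not shown: of 8 tests of the 200 genes most changed with age in the other background, 0 passed by fry. The smallest adjusted p was 0.796, for genes that fall with age, in Tg(Kat6b) at E15.5, although 173 of 200 lay above 0 (median 0.13). It was 0.0502 with a replicate block and 0.574 and 0.949 for sets of 100 and 500 genes.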

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

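The tests of other splits of the libraries were planned, and the tests of Dupd1, of Nr2e1 and Otx1 and of labelled knockout replicates 3 and 4 were chosen only after the result was seen. In 7 of 101 groups of values tested, the highest or lowest library lay far from the rest by Dixon's test, which chance does in about 1 in 20 groups. Ribosomal RNA took 0.211% of the counts in C57BL/6 wild-type replicate 1 at E15.5 (next 0.116%), 19.5% in labelled knockout replicate 3 at E15.5 (next 0.531%), 0.355% in FVBxBALB/c wild-type replicate 4 at E12.5 (next 0.0911%) and 0.729% in Tg(Kat6b) replicate 2 at E15.5 (next 0.238%). The 50 most abundant genes took 27.9% of the counts in labelled knockout replicate 3 at E15.5, against 8.56% in the next library. Otx1 was lowest in FVBxBALB/c wild-type replicate 2 at E15.5, at 29.6 CPM (next 32.2), and Ttr highest in replicate 3 of the same group, at 428 CPM (next 2.81). Outside the named genes, labelled knockout replicate 3 at E15.5 had 2.002% of its counts in rows that name no gene, against at most 0.4933% in the wild-type libraries. Of these unnamed rows 181 were tested in C57BL/6 and 169 in FVBxBALB/c, and by edgeR 0 passed in any genotype comparison, with 9, 4, 9 and 3 at an unadjusted p under 0.05.

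Other splits of the same libraries were set beside the real groups. For the E15.5 transgenic comparison 1 of 35 splits called as many genes (real 2, highest other 0) and 1 of 35 as many lists (real 2, highest other 0). The 2 genes are Kat6b and Dupd1, and without them the real groups called 0 genes and 0 lists. These splits therefore show the transgene and its neighbour, and do not speak for a wider response. Chance is argued against for the age change in C57BL/6 (1 of 56, real 9157, highest other 17). The same holds in FVBxBALB/c (1 of 35, real 7798, highest other 467). Both shares are the smallest that the splits allow, and the splits by age do not keep litters. For the set of genes lower in the labelled knockout at E15.5, 1 of 35 splits of the transgenic libraries had a fry p as small as the real 0.00435 (smallest other 0.0459), and 1 of 35 gave as many as the 33 genes opposite at E15.5 (highest other 31). A share of 1 of 35 is the smallest that these splits allow, and it argues against chance in the transgenic labels alone. The margin was narrow for the 33 genes, whose count was 17 without Tg(Kat6b) replicate 1 and 14 without labelled knockout replicates 3 and 4. The same exact permutation gave p = 0.114 for the correlation across genes, and the labelled knockout was not permuted. No litters are given for FVBxBALB/c, so these splits could not keep them. For the lists of the E15.5 labelled knockout 4 of 100 splits called as many (real 1, highest other 1), but these ignore the litters, and the splits that keep them are too few for a share under 0.05. Chance was not excluded for the E12.5 transgenic count (7 of 35; real 2, highest other 4640), its lists (7 of 35; real 1, highest other 11) or the 35 genes opposite at E12.5 (16 of 35; highest other 179). Counts of 0 are reached by every split: for the E15.5 labelled knockout 100 of 100 (highest other 74) and for the difference between ages 100 of 100 in each genotype (highest other 1678 and 2890). Splits of the E12.5 labelled knockout are too few for a share under 0.05 (2 of 10 for genes, real 1, highest other 2483; 10 of 10 for lists, real 0, highest other 9).

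The splits that call the most genes point to a structure of the E12.5 samples. In C57BL/6 the split with 2483 genes sets wild-type replicate 1 and labelled knockout replicates 1 and 3 against the others, which puts both embryos of 1 litter on the same side, and the pan-neuronal genes deviated by -0.571, -0.353 and -0.104 in these and by 0.227 to 0.458 in the others. In FVBxBALB/c the split with 4640 genes sets wild-type replicates 1, 2 and 3 and Tg(Kat6b) replicate 1 (0.377, 0.0287, 0.09 and 0.382) against wild-type replicate 4 and Tg(Kat6b) replicates 2, 3 and 4 (-0.56, -0.167, 0.019 and -0.19). By the labels the C57BL/6 embryos at E15.5 form 5 litters of a wild-type and a labelled knockout embryo. At E12.5 they form 2 litters, since replicates 3 and 4 of both genotypes share 1. Of the 100 splits drawn at E15.5 (126 possible) 12 of 16 possible ones part every litter evenly, and the highest other of these called 0 genes and 0 lists (real 0 and 1). With a replicate block 0 genes and 0 lists passed there. With a litter block 1 gene, Nr2e1, passed (adjusted p = 0.0302 by edgeR) and 0 lists. Both blocks are the same at E15.5, so these results differ only through the E12.5 libraries of the shared model. At E12.5 6 of 10 splits part every litter evenly, and the highest other of these called 0 genes and 0 lists (real 1 and 0). With a replicate block or a litter block 0 genes passed at E12.5.

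Dupd1 rose with Kat6b in every Tg(Kat6b) library, while the wild-type libraries held at most 2 counts. A constant share of Kat6b transcripts running on into Dupd1 is argued against, since over pooled counts the ratio of Dupd1 to Kat6b was 30.9 times as high in Tg(Kat6b) as in wild type at E12.5 (95% interval from counting error alone 11.9 to 114; lower bound at E15.5 16.9). In each library Dupd1 counts were 0.445% or more of Kat6b counts in Tg(Kat6b) and 0.0251% or less in wild type at E12.5, and 0.509% or more and 0% at E15.5. A rise of all genes around Kat6b is argued against as well, since the median log2 fold change of the 18 other tested neighbours was -0.0197 (SD 0.222, highest 0.503) at E12.5 and 0.016 (SD 0.172, highest 0.275) at E15.5. It stays open, as an untested hypothesis, that the transgene may carry Dupd1 sequence or run on into it where the native gene does not; the extent of the transgene is not given in the sources used here.

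Nr2e1 and Otx1 were lower in the labelled knockout and higher in Tg(Kat6b) at E15.5, which may reflect opposite effects of both genotypes. The following explanations were tested on Nr2e1 alone and give no verdict for Otx1. Labelled knockout replicates 3 and 4 alone are argued against (Nr2e1 at -0.394, SE 0.0894, without both). A different share of apical progenitors could not be decided. With age, as progenitors give way to neurons, some of these markers rose and others fell, so their median does not follow that share. The marker median was 0.00334 (SD 0.167) in the labelled knockout and 0.117 (SD 0.171) in Tg(Kat6b), against Nr2e1 at -0.473 and 0.402. In either comparison 0 of the 23 markers lay beyond Nr2e1. Cell cycle and intermediate progenitor genes did lie mostly below 0 in the labelled knockout and above 0 in Tg(Kat6b), though neither list passed. A different share of non-cortical tissue is argued against too (difference of both effects on Nr2e1 -0.828 with the marker score in the fit). Asked at E12.5 by edgeR, the difference of the effects held for Nr2e1 (-0.52, SE 0.137; adjusted p = 0.00126 over both genes, 0.53 over all genes), with Tg(Kat6b) at 0.249, or 0.162 without its replicate 3. For Otx1 it was not shown (-0.23, SE 0.182, adjusted p = 0.222), and its value in Tg(Kat6b) at E12.5, -0.19 (SE 0.116; -0.291 without its replicate 3 and -0.115 without 4), was below 0, against 0.48 at E15.5. Each C57BL/6 litter at E15.5 holds 1 embryo of each genotype, while the litters of FVBxBALB/c are not given in the sources used here and stay open, as does whether either effect depends on the background.

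Labelled knockout replicates 3 and 4 at E15.5 stood apart from the other 8 libraries. Ribosomal RNA as their shared feature is argued against, since replicate 4 had 0.531% against 19.52% in replicate 3 and up to 0.3825% in the other 8 C57BL/6 libraries at E15.5. A shift of every labelled knockout library is argued against as the cause, since 3 of the 5 lay among the wild-type libraries on the second component. An effect of the labelled genotype in only some embryos cannot be excluded by this, since replicates 3 and 4 are both labelled knockouts. Meningeal and mesenchymal tissue may account for part of the distance of replicates 3 and 4. The lower of both lay 2.02 (log2) above the highest other labelled knockout library in the median of these markers, with Col3a1 at 70.6 and 67.3 CPM. Markers of other brain regions were high too (Tcf7l2 at 209 and 200 CPM) but also in wild-type replicate 2 (191), and whether the dissection differed was not tested.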

How the results depend on the processing

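Alternatives chosen after seeing the data were the ribosomal RNA genes left out, 1 surrogate variable, the non-cortical marker covariate, both replicates 5 left out, labelled knockout replicates 3 and 4 left out, the lists without Kat6b and Dupd1, and most settings of the list and set tests; the other tests were planned. The count of genes changed in the labelled knockout at E12.5 (1) was 5 with DESeq2, 0 with a replicate block, the Y-linked covariate, a litter block and a fit of only the 2 groups, 2 with the non-cortical covariate and 0 to 2 with 1 library left out (2 without replicate 1 of either genotype and 0 without any other). At E15.5 the count (0) was 7 with DESeq2, 1 with limma-voom, 1 with a litter block, 2 in a fit of only the 2 groups and 1 with all 32 libraries. For Tg(Kat6b) at E12.5 (2) it was 6 with DESeq2 and 832 with limma-voom, and at E15.5 (2) it was 7 with DESeq2 and 4 in a fit of only the 2 groups or of all 32 libraries. The difference between ages (0) was 1 with DESeq2 and 1 with limma-voom in either genotype. The age change in FVBxBALB/c (7798) was 3815 with a replicate block and 3174 with 1 surrogate variable, and 7595 to 9309 in C57BL/6 (9157) over 15 settings. For the labelled knockout at E15.5 the replicate and litter blocks are the same, and their counts differ through the E12.5 libraries of the shared model. The cause was not tested in the other cases.

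The lists of the labelled knockout at E12.5 (0) were 0 to 2 with 1 library left out, with 2 without labelled knockout replicate 1 (SOX family, adjusted p = 0.00183, and area patterning, 0.000392). Those at E15.5 (1, the SOX family) were 0 with a replicate block (adjusted p = 0.305), the Y-linked covariate (0.0608), a litter block (0.252), both replicates 5 left out (0.132), labelled knockout replicates 3 and 4 left out (0.137), the non-cortical covariate (0.0654) and 1 surrogate variable (0.0563). With 1 library left out they were 0 to 1, with an adjusted p of 0.0292 to 0.122; only without wild-type replicate 3 was it below 0.05. In Tg(Kat6b) at E12.5 (1) they were 0 without Kat6b and Dupd1, with no filter, a replicate block or an estimated correlation, and 0 to 2 with 1 library left out (0 without Tg(Kat6b) replicate 4 and 2 without replicate 1). At E15.5 (2) they were 0 without Kat6b and Dupd1. Leaving out those genes or libraries is itself the cause there, and elsewhere the cause was not tested.

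Of the 8 sets exchanged between the genotypes (1 passed), 4 passed with an estimated correlation, the filter at CPM above 1, a replicate block or a litter block. There were 2 with no filter, the Y-linked covariate, 1 surrogate variable, the non-cortical covariate or both replicates 5 left out. The number was 0 with the ribosomal RNA genes left out or labelled knockout replicates 3 and 4 left out, and 0 to 3 with 1 library left out. The set lower in the labelled knockout at E15.5 had an adjusted p of 0.0554 and 0.517 in those last 2 settings and 0.0132 to 0.235 with 1 library left out. The genes opposite at E12.5 (35) were 23 with 1 surrogate variable, 17 with the non-cortical covariate and 12 to 68 with 1 library left out. At E15.5 (33) they were 14 without labelled knockout replicates 3 and 4 and 17 to 49 with 1 library left out. The correlation across genes ranged from -0.188 to -0.00256 at E12.5 and from -0.217 to -0.112 at E15.5 with 1 library left out, and from -0.136 to -0.0917 and -0.251 to -0.0327 over 4 and 5 other settings, the last without labelled knockout replicates 3 and 4. Its exact permutation p was 0.0286 without Tg(Kat6b) replicate 4 at E12.5, where r was -0.188, and without labelled knockout replicate 3 at E15.5, where r was -0.152. The cause was not tested.

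Over 223 single-gene results followed through the settings, with 4943 values, 4879 kept their call and direction, 21 no longer passed, 40 newly passed and 3 reversed. A gene that never passed and kept its sign counts among the 4879. In the genotype comparisons only Stac, Kat6b and Dupd1 passed in the main fit. The count therefore does not show that the other genotype values are stable. Among those no longer past the threshold were Stac (8 values) and Gpr17 with age in FVBxBALB/c (9 values). Of 123 such results in the genotype comparisons, 33 moved by over 1.5 times with 1 library left out. Reversed were Kat6b in the labelled knockout at E15.5 (0.0395), never called, with both replicates 5 left out (-0.0102) and without wild-type replicate 3 (-0.00168; range with 1 library left out -0.00168 to 0.0831), and Col3a1 there without labelled knockout replicates 3 and 4 (-0.867); the cause was not tested. In FVBxBALB/c, where no litters are given, residuals of libraries sharing a replicate number correlated at -0.116 to 0.604 at E12.5 and -0.141 to 0.0847 at E15.5. Beyond the values given, a replicate block changed no list, and the counts for Tg(Kat6b) became 3 and 3. Depth limits genes near the filter: Dupd1 in wild type, at 0 to 2 counts per library, gives only a bound on its fold at E15.5.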

Other observations

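The direct comparison of both genotype effects in 1 model was a test chosen only after the result was seen, and the genes named for age here were chosen after their values were seen. Age moved members of single families apart in both wild-type backgrounds. In the SOX family Sox5, a regulator of deep-layer neurons, rose (1.75 in C57BL/6 and 1.65 in FVBxBALB/c, log2), while the glial and progenitor factor Sox9 (-1.06 and -0.90) and Sox13 (-0.93 and -1.22) fell. Of its 17 members 5 rose and 9 fell in C57BL/6 (adjusted p = 0.00275, and adjusted p = 0.607 with an estimated correlation), and 5 rose and 7 fell in FVBxBALB/c (adjusted p = 0.0722). Apical progenitor genes split likewise, with 9 and 8 of 23 risen and 12 and 12 fallen; the cell surface protein gene Prom1 fell (-1.20 and -1.17). Axon guidance and adhesion genes rose in 17 and 13 of 32 and fell in 5 and 7, with the cadherin Cdh13 at 3.38 and 3.28, the semaphorin receptor Nrp1 at 1.53 and 1.48 and the nectin Nectin3 at -1.20 and -1.01.

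Markers of diencephalon, midbrain and hindbrain fell with age in 6 of 21 genes in C57BL/6 (median -1.46, adjusted p = 0.0372, and 0.775 with an estimated correlation) and in 17 of 18 in FVBxBALB/c (median -4.36, adjusted p = 0.000412, and 0.400). Among them Gata2 (-2.12 and -3.63) and Barhl2 (-2.21 and -2.63) fell in both, and Pax7 fell in FVBxBALB/c (-5.61, SE 0.623) and did not pass in C57BL/6 (-1.45), where it did so in 2 of 15 other settings (-5.667 to -0.5131) and, at -4.043, without E15.5 wild-type replicate 2 (-4.043 to -0.9744 with 1 library left out). Whether the backgrounds differ in this was not tested, and the labelled tissue changes along with age.

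With all 32 libraries in 1 edgeR model, the difference between the labelled knockout and Tg(Kat6b) effects was past the threshold for 2 genes at E12.5, Kat6b and Stac, and for 3 at E15.5, Kat6b, Nr2e1 (-0.87, SE 0.122, adjusted p = 0.000575) and Otx1 (-1.05, SE 0.166, adjusted p = 0.0039). At an unadjusted p under 0.05 there were 1184 and 832 genes. Background and sequencing batch are constant within each genotype effect, but the effects come from different backgrounds.

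By the X-linked transcript Xist, 2 of the 32 libraries came from female embryos, wild-type replicate 4 of C57BL/6 at E12.5 (1080 CPM) and wild-type replicate 3 of FVBxBALB/c at E15.5 (818), against at most 2.05 in the others. Their Y-linked genes summed to 0.796 and 1.22 CPM, against 164 to 341.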
